A study of Mus musculus with 126 samples.

How the data were processed

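RNA from mouse colon was measured in 126 libraries, 3 at each of 6 zeitgeber times (ZT, hours after lights on) in 7 conditions. Per the labels, RNA was extracted with TRIzol, poly(A) RNA was selected, and libraries were made with the Illumina TruSeq stranded mRNA kit. The authors aligned reads with TopHat2 2.1.1 to genome build mm10 and quantified genes with Cufflinks 2.2.1, per the labels. The deposited tables, one for each condition with 24883 genes each, hold FPKM (fragments mapped per kilobase of transcript, scaled to the mapped fragments of the library). That unit was read from Cufflinks being the only quantifier named and from the values, which were not whole, never negative and summed to different totals per library. The annotation, filters and normalization options of Cufflinks are not given in the sources used here, nor is whether the 7 tables were normalized together. Comparisons between conditions therefore cross tables, while rhythms were fitted within a table. Columns, all used, name the time and replicate, and the table sets the condition.

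Sequencing depth per library is not given in the sources used here, so no counting interval was computed. Relative numbers of mapped reads were estimated from the steps that single reads leave in the FPKM of low genes. Replicates are separate libraries, and whether each came from its own animal is not stated for every group; the p-values therefore measure the spread between these samples. No pair of libraries was identical, and the median absolute log2 difference between replicates ran from 0.089 to 0.531 (median 0.188).

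Each library was divided by a median-of-ratios scale factor over 6966 genes, computed across all 7 tables, and values were analysed as log2 of rescaled FPKM plus 0.5. The 11377 rows with a mean rescaled FPKM of at least 1 in at least 1 condition were tested. Rows sharing a symbol with another row (280 symbols on 817 rows, 113 of them tested) were kept apart and their identity is uncertain. Genes that overlap others, antisense genes and close paralogs may share reads and carry the same uncertainty. Coordinates and transcript lengths came from GENCODE vM21 on the same build, which gave a length for 96.2% of tested rows.

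limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options) was fitted to the 54 libraries of the 3 genotypes (36 residual degrees of freedom) and, separately, to the 72 libraries of the 4 diet and feeding groups (48), with 1 mean per condition and time. A level difference is the difference of condition means averaged over the 6 times, tested with limma's moderated test. A rhythm is a 24 h cosine and sine contrast over the 6 time means, tested with a limma F test with 2 degrees of freedom, and a rhythm difference is the same test on the difference of these contrasts between conditions. Amplitudes are the log2 distance from mean to peak, peak times are in hours of ZT, and ± gives the standard error unless SD is named. All p-values were 2-sided and adjusted by Benjamini-Hochberg, with 0.05 as the threshold. Clock gene phase shifts are circular means over clock genes rhythmic in both conditions, with the SD over the 3 replicate numbers and no test.

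Sets of genes for pathways, cell types and gut regions (39 lists) were tested where at least 3 members were measured (30 lists). Level shifts were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and rhythms with Fisher's exact test against all other tested genes, adjusted over lists within a comparison. Counts of members passing are given over all genes tested and adjusted over the list alone. The tests, the gene lists, the settings to be tried as alternatives and the naming rule were fixed before the data were examined. The rule names, for each level comparison, the 10 largest rises and falls that pass the threshold with 1 sign at all 6 times, the clock genes, Scnn1a, Scnn1b, Scnn1g, Sgk1 and Nr3c2, and up to 4 members per list with the smallest adjusted p; for rhythms it names the 10 largest differences or amplitudes and the same list members. Some genes that the rule names are not reported here. The rule leaves out predicted genes (Gm and Rik symbols) and immunoglobulin and T cell receptor segments.

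The tests were checked on simulated data of this layout with independent noise per gene. Of genes given a log2 change of 0.5 between Bmal1 knock out and wild type 88.2% were recovered, 93% for amplitudes and 66% for rhythm differences of that size. For feeding these were 89.7, 87 and 62%. Of 11177 unchanged genes 10 (feeding, 11) were called for level, which is no bound on false calls from library-wide deviations.

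The alternatives fixed beforehand were other pseudocounts, other filters on low values, FPKM as deposited, quantile normalization, limma array weights, a replicate block, leaving out each replicate number and each library, fits of the compared libraries alone and time as a factor. A length score per library (the slope, over genes, of its deviation from the gene mean on log2 transcript length), leaving out libraries with a scale factor under 0.6, leaving out a pair of times and a model with cosine and sine terms were added after seeing the data. Other splits of the samples were drawn 100 at a time, the real split included. Tables were read with data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9 in Python 3.11.15.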

Results

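Gene expression in the mouse colon was followed over the day in 3 genotypes and in 4 combinations of dietary salt and feeding time. Wild-type mice, mice lacking Bmal1 in the gut and mice lacking the mineralocorticoid receptor (MR) in the gut ate chow freely. Both knock outs were 8 to 12 weeks old per the labels, which give no age for wild type, so whether ages matched is unknown. The feeding groups were 8-week-old male C57BL/6 mice given low- or high-salt food at night or by day only, under 12 h of light and 12 h of darkness. Each of the 7 conditions had 18 libraries, 3 at each of ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20. Each condition has its own table, so level differences cross tables while rhythms lie within one. The sum of FPKM per library ran from 158029 (Bmal1 knock out) to 660895 (low salt day fed).

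The libraries differed in yield. The scale factor had a median of 1.22 in wild type, 0.586 in Bmal1 knock out, 1.03 in MR knock out, 1.21 in low salt night fed, 1.21 in low salt day fed, 0.941 in high salt night fed and 1.21 in high salt day fed. It lay under 0.6 in 14 libraries: Bmal1 knock out at ZT0 (1), ZT12 (3), ZT16 (3) and ZT20 (2), and high salt night fed at ZT8 (3) and ZT12 (2). Rows annotated as ribosomal RNA made up a median of 1.72% of the summed FPKM in these 14 libraries and 0.148% in the other 112. The length score averaged 0.17 ± 0.105 (SD, n = 18) in wild type and -0.102 ± 0.138 in Bmal1 knock out, with the other conditions between -0.066 and 0.007.

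**Figure D1:**
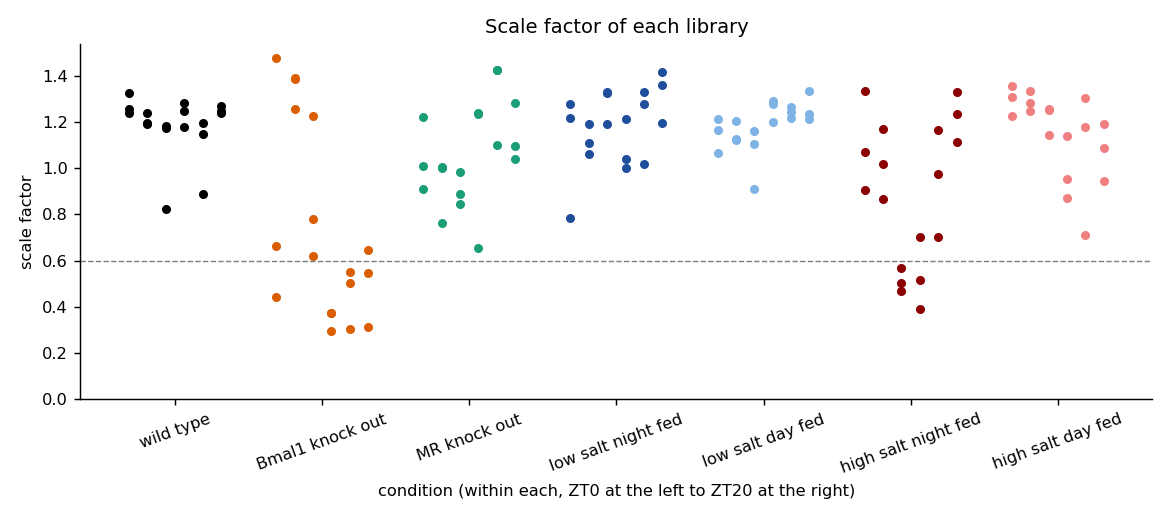
Scale factor of the 126 libraries (1 point each) by condition, with time running from ZT0 (left) to ZT20 (right) within each. The dashed line marks 0.6.

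The targeted genes were examined first. Arntl, the gene for the clock activator BMAL1 (chromosome 7, 113207465 to 113314126, mm10), had a rescaled FPKM of 9.32 ± 6.29 (SD, n = 18; range 2.25 to 19.2) in wild type and 4.41 ± 0.992 (2.87 to 6.28) in Bmal1 knock out. Its level fell by 0.68 ± 0.09 on the log2 scale (adjusted p = 1.4e-08), with lower values at 3 of 6 times. The ranges overlapped, and wild-type Arntl itself went from 17.4 at ZT0 to 2.62 at ZT12. The wild-type amplitude was 1.43 ± 0.09 with a peak at ZT23.9, against 0.24 ± 0.09 in the knock out, where the rhythm did not pass (adjusted p = 0.055). FPKM covers the whole gene and does not show which part was deleted. With libraries of low scale factor left out, cosine and sine terms and the length score as a covariate, all chosen after seeing the data, the level call ended at a log2 difference of -0.28. Nr3c2, the gene for MR (chromosome 8, 76899442 to 77245012), was at 15.1 ± 4.9 (7.05 to 23.2) in wild type and 3.05 ± 0.988 (1.66 to 5.33) in MR knock out, with no overlap, and fell by 2.11 ± 0.15 (adjusted p = 1.71e-14, lower at 6 of 6 times).

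The wild-type colon had a strong clock, with 2011 of 11377 genes rhythmic (17.7%). Of 16 measured clock genes 14 were rhythmic (adjusted over the list alone, 16, list adjusted p = 3.52e-08). Nr1d1, a repressor of Bmal1 (chromosome 11, 98767932 to 98775333), had an amplitude of 2.63 ± 0.12 and peaked at ZT8.79. Dbp, an output transcription factor of the clock, peaked at ZT11.8 (amplitude 2.78 ± 0.14), and Per2, a repressor of CLOCK and BMAL1, at ZT16.5 (1.77 ± 0.11). Cell cycle genes were rhythmic in 20 of 21 cases (adjusted over the list alone, 21, list adjusted p = 4.29e-13), with Ccna2, a cyclin of S and G2 phase, peaking at ZT4.15. Genes of sodium uptake and the aldosterone response were rhythmic in 9 of 15 cases (alone, 11, list adjusted p = 0.00178) around ZT14.6. Among these, Scnn1g, the gamma subunit of the epithelial sodium channel, peaked at ZT12 (0.65 ± 0.09). Genes of endoplasmic reticulum stress were rhythmic in 12 of 14 cases (alone, 12, list adjusted p = 5.78e-07) around ZT18.1. The wild-type count ran from 375 with FPKM as deposited to 7444 with array weights.

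**Figure D2:**
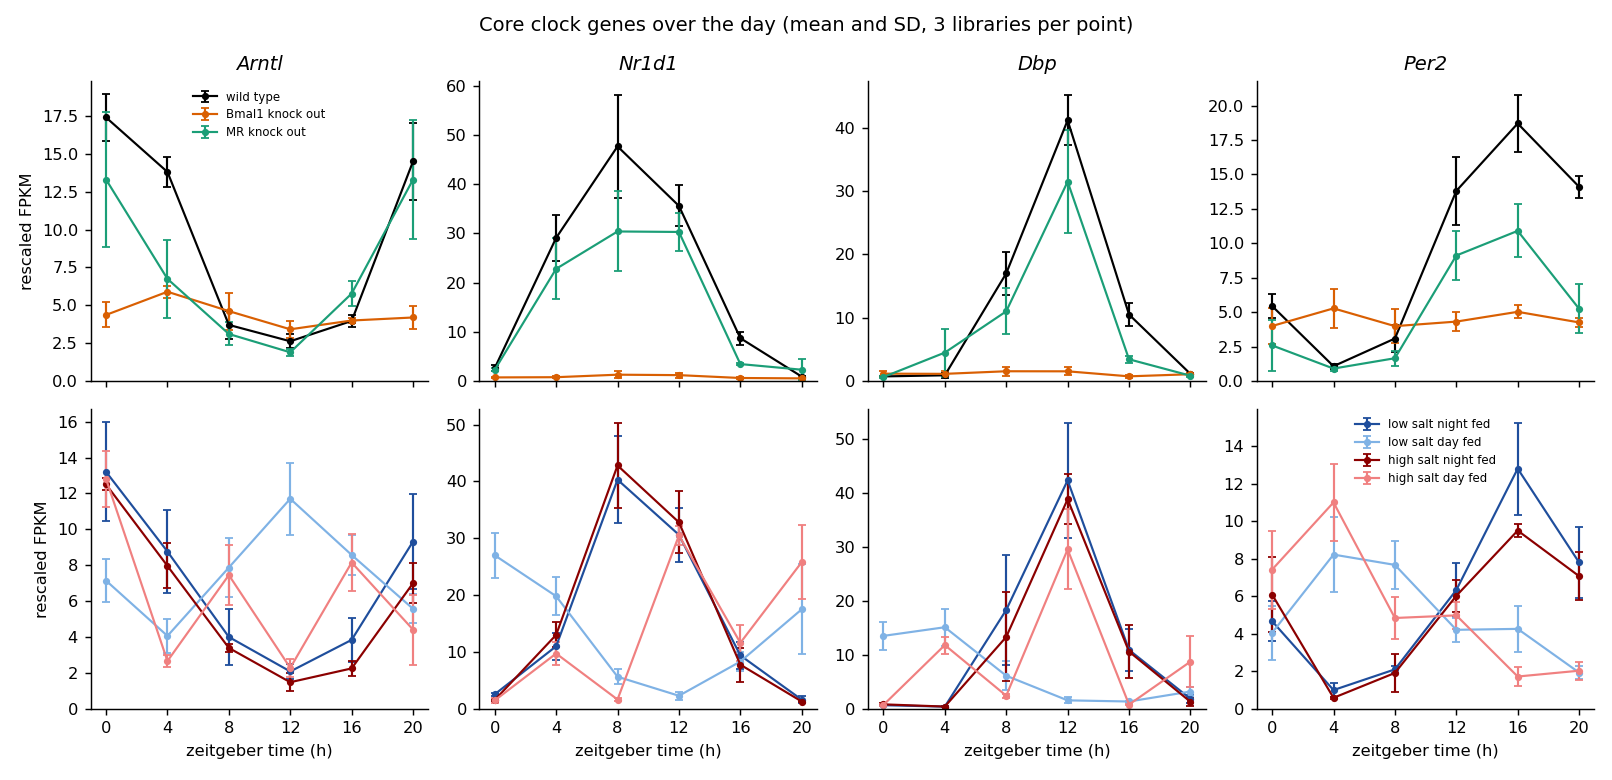
Rescaled FPKM of Arntl, Nr1d1, Dbp and Per2 against zeitgeber time in hours (means and SD of 3 libraries). Upper panels show the 3 genotypes and lower panels the 4 feeding groups. The Bmal1 knock out line is nearly flat, the low salt day-fed line peaks at other times than the night-fed lines, and for Arntl, Nr1d1 and Dbp the high salt day-fed line meets the night-fed lines at ZT0 and ZT12.

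The comparison of Bmal1 knock out with wild type asks what the intestinal clock contributes to the colon's daily programme. Rhythms of the clock genes were reduced or lost: 15 of 16 differed in rhythm (adjusted over the list alone, 15, list adjusted p = 8.48e-06). The amplitude of Nr1d1 was 0.35 ± 0.12, of Dbp 0.22 ± 0.14 (adjusted p = 0.331) and of Per2 0.03 ± 0.11 (adjusted p = 0.97). In level, 4 clock genes rose and 11 fell (alone, 4 and 11). Nr1d1 fell by 3.12 ± 0.12, Nr1d2 by 2.79 ± 0.10, Per3 by 2.03 ± 0.14 and Dbp by 1.69 ± 0.14, while Cry1 rose by 1.19 ± 0.08 and Nfil3 by 1.06 ± 0.11. Npas2 rose by 0.76 ± 0.07, and with FPKM as deposited it turned to -0.03. Nr1d1, Nr1d2, Per3 and Cry1 kept 1 sign at all 6 times, Npas2 was higher at 5, and Nfil3 and Dbp followed the direction at 4. Cry2 did not pass (-0.06 ± 0.07, adjusted p = 0.466). The clock list as a whole did not pass in level (camera adjusted p = 0.171, 0.707 with an estimated correlation).

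Of the sodium uptake and aldosterone genes 11 of 15 fell and 1 rose (alone, 11 and 1, camera adjusted p = 0.015). This list and the 3 that follow were each at adjusted p = 0.673 with an estimated correlation, and its call ended with array weights (adjusted p = 0.0562). Hsd11b2, which protects MR from glucocorticoids, fell by 1.32 ± 0.12, and Sgk1, the aldosterone-induced kinase, by 0.99 ± 0.13. The channel subunits Scnn1a, Scnn1b and Scnn1g fell by 0.78 ± 0.08, by 0.39 ± 0.10 and by 0.87 ± 0.09. Of these, Sgk1 was lower at 5 of 6 times and Scnn1b at 4, and the others at all 6. Where Scnn1g had a mean under 0.5 FPKM, as in both knock outs and both high salt groups, the 0.5 added before the log compressed its fold changes and amplitudes. Nr3c2 itself fell by 1.25 ± 0.15. Genes of sodium-hydrogen and chloride-bicarbonate exchange fell in 11 of 13 cases (alone, 11, camera adjusted p = 0.00243). Slc26a3, the colon's main chloride exchanger, fell by 1.99 ± 0.13, Car2, a carbonic anhydrase, by 1.30 ± 0.07, and Slc9a2, a sodium-hydrogen exchanger, by 1.35 ± 0.13. Xenobiotic metabolism genes fell in 12 of 16 cases with 1 rise (alone, 12 and 1, camera adjusted p = 0.0105). The drug efflux pump Abcb1a fell by 2.12 ± 0.15, the esterase Ces2c by 1.47 ± 0.11 and the P450 reductase Por by 1.14 ± 0.07. Genes of fatty acid oxidation fell in 13 of 20 cases with 1 rise (alone, 13 and 1, camera adjusted p = 0.0193). Cpt1a, which takes fatty acids into mitochondria, fell by 1.37 ± 0.14. Among the 10 largest falls were those of Trim12a (-3.90 ± 0.11), Cyp4b1 (-3.49 ± 0.23), Ces1d (-2.58 ± 0.15) and the peptide transporter Slc15a1 (-2.58 ± 0.16).

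Interferon response and MHC class II genes were higher in Bmal1 knock out, and each list call here stood at adjusted p = 0.673 with an estimated correlation. All 14 interferon response genes rose (alone, 14; mean log2 2.06, camera adjusted p = 4.01e-09), with Isg15 up by 3.36 ± 0.25 (99.8 against 9.53 FPKM) and Oasl2 by 2.75 ± 0.19. All 7 MHC class II genes rose (alone, 7, camera adjusted p = 0.00243). Cd74 rose by 3.18 ± 0.39 and H2-Aa by 3.22 ± 0.41. By limma 0 of 5 T cell and 0 of 4 inflammatory genes passed (alone, 0 and 0; unadjusted p under 0.05, 0 and 0). The largest rises also held the secreted defence genes Ang4 (4.90 ± 0.67), Itln1 (4.65 ± 0.50) and Retnlb (4.59 ± 0.44), the phospholipase Pla2g4c (5.04 ± 0.57), Ifi27l2a (4.25 ± 0.36) and Hddc3 (4.05 ± 0.09). The antimicrobial lectin Reg3b fell by 2.96 ± 0.40. Cell cycle genes rose in 14 of 21 cases with 1 fall (alone, 12 and 0, camera adjusted p = 0.0041), and with FPKM as deposited their mean turned to -0.59 and the call ended (adjusted p = 0.0653). Birc5 rose by 1.03 ± 0.10 and Aurka by 0.52 ± 0.07 (-0.30 with FPKM as deposited), and 14 members differed in rhythm (alone, 14, list adjusted p = 0.0125). Ribosomal protein genes rose in 14 of 15 cases (alone, 14 and 1 fall; camera adjusted p = 0.00026), but their mean turned from 0.53 to -0.08 with quantile normalization, to -0.07 with the length score as a covariate and to -0.37 with FPKM as deposited. Rps19 rose by 1.30 ± 0.16 and Rpl8 by 0.80 ± 0.11, each higher at 5 of 6 times. Immediate early genes (8 of 10 lower), distal colon Hox genes (4 of 4 lower), and crypt base (6 of 7 lower, 1 higher), surface colonocyte (5 of 9 lower, 1 higher), goblet (5 of 9 higher, 2 lower), tuft (3 of 4 higher), enteroendocrine (5 of 8 lower, 2 higher) and smooth muscle genes (2 of 3 lower, 1 higher) had the same counts alone and did not pass camera (adjusted p = 0.185, 0.301, 0.211, 0.211, 0.201, 0.211, 0.949 and 0.949; at least 0.707 with an estimated correlation).

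In total 9135 genes differed in level between Bmal1 knock out and wild type, 3534 higher and 5601 lower (38.7% higher). Rhythmic genes numbered 6450 in the knock out (56.7%), and 3546 differed in rhythm, Dbp among them. Across all genes the median log2 difference was -0.13, and it was -0.89 with FPKM as deposited, which left 3.7% of the calls higher, -0.03 with quantile normalization and 0.01 with the length score. A share of 51.6% was higher with the length score as a covariate (4087 genes) and 50% with low-scale libraries left out and cosine and sine terms as well (892 genes). With cosine and sine terms 6283 genes were rhythmic and 3323 differed in rhythm, and 754 and 279 with these terms and without the 9 libraries of low scale factor, which sat at ZT12, ZT16, ZT20 and ZT0. The 6 clock genes rhythmic in both genotypes, with Nr1d1 among them, had a mean shift of 0.36 h (SD 1.29, range -4.18 to 6.33), which moved to 5.93 h without replicate number 2 and to -10.4 h with FPKM as deposited.

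The comparison of MR knock out with wild type asks which colon genes depend on aldosterone signalling. Of the sodium uptake and aldosterone genes 12 of 15 fell and no member rose (alone, 12, camera adjusted p = 1.4e-06, adjusted p = 0.101 with an estimated correlation). Beside Nr3c2, Scnn1b (chromosome 7, 121865038 to 121918514) fell by 1.55 ± 0.10 (0.481 against 2.27 FPKM), Hsd11b2 by 1.55 ± 0.12 and Sgk1 by 1.43 ± 0.13. Scnn1g fell by 0.87 ± 0.09 (lower at 5 of 6 times) and Fkbp5, a steroid receptor co-chaperone, by 0.89 ± 0.06, the others named here being lower at all 6. Scnn1a, the alpha subunit, did not pass (-0.04 ± 0.08, adjusted p = 0.675). The largest fall was that of Fxyd4, a regulator of the sodium pump in the colon, by 4.69 ± 0.30 (3.71 against 70.6 FPKM), and Best2, an anion channel of goblet cells, fell by 2.06 ± 0.16. Atp12a, the colonic proton-potassium pump, fell by 1.42 ± 0.20 and peaked at ZT19.9 against ZT13.9 (adjusted p = 0.00412).

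Interferon response and MHC class II genes were higher in MR knock out. All 14 interferon response genes rose (alone, 14, camera adjusted p = 5.7e-16, adjusted p = 0.101 with an estimated correlation). Isg15 rose by 3.23 ± 0.25, Oasl2 by 2.88 ± 0.19 and Ifi27l2a by 4.89 ± 0.36. MHC class II genes rose in 7 of 7 cases (alone, 7, camera adjusted p = 3.2e-09, adjusted p = 0.101 with an estimated correlation). H2-Aa rose by 5.07 ± 0.41 and Cd74 by 4.82 ± 0.39 (316 against 11 FPKM). T cell genes rose in 4 of 5 cases (alone, 4, camera adjusted p = 0.0486, adjusted p = 0.602 with an estimated correlation), a call that ended with a pseudocount of 0.1 (adjusted p = 0.0836) and array weights (0.0999). Antimicrobial and epithelial defence genes rose in 9 of 15 cases and fell in 2 (alone, 9 and 2, camera adjusted p = 0.000543, 0.101 with an estimated correlation). Ang4 rose by 4.56 ± 0.67, Itln1 by 3.99 ± 0.50, the DUOX2 partner Duoxa2 by 2.34 ± 0.20 and Nos2 by 1.38 ± 0.16. Reg3b fell by 2.09 ± 0.40.

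Immediate early genes fell in all 10 cases (alone, 10, camera adjusted p = 0.000276, adjusted p = 0.477 with an estimated correlation). Fosb fell by 1.96 ± 0.26, Nr4a1 by 1.90 ± 0.21 and Egr1 by 1.43 ± 0.20, and Arc fell by 2.21 ± 0.21, each at 6 of 6 times. Surface colonocyte genes rose in 6 of 9 cases with 1 fall (alone, 6 and 1, camera adjusted p = 0.00331, adjusted p = 0.207 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.134). Krt20, a keratin of mature surface cells, rose by 1.0 ± 0.08. Crypt base genes fell in 6 of 7 cases with 1 rise (alone, 6 and 1, camera adjusted p = 0.0499, adjusted p = 0.516 with an estimated correlation), with the stem cell gene Lgr5 at -0.93 ± 0.11 and Sox9 at -0.68 ± 0.08. That call ended with a pseudocount of 0.1 (adjusted p = 0.0595), array weights (0.066) and FPKM as deposited (0.0798). All 4 tuft cell genes rose (alone, 4, camera adjusted p = 0.000297, adjusted p = 0.153 with an estimated correlation). Alox5, a lipoxygenase, rose by 0.91 ± 0.11 and the taste channel Trpm5 by 0.82 ± 0.11. Enteroendocrine genes fell in 6 of 8 cases (alone, 6, camera adjusted p = 0.0486, adjusted p = 0.602 with an estimated correlation), a call that ended with a pseudocount of 0.1 (adjusted p = 0.0513) and array weights (0.0997). The hormone genes Insl5 and Gcg fell by 1.34 ± 0.17 and by 1.35 ± 0.18. All 4 distal colon Hox genes fell (alone, 4, camera adjusted p = 0.0121, adjusted p = 0.377 with an estimated correlation), a call that ended with array weights (adjusted p = 0.074). Hoxd13 was at -1.21 ± 0.14 and Hoxb13 at -0.82 ± 0.14. Cell cycle genes rose in 8 of 21 cases with 1 fall (alone, 8 and 1, camera adjusted p = 0.0121) and cholesterol synthesis genes in 8 of 20 with 2 falls (alone, 7 and 2, camera adjusted p = 0.0499). Both stood at adjusted p = 0.602 with an estimated correlation, and with FPKM as deposited their means turned to -0.03 and -0.07 and both calls ended (adjusted p = 0.0679 and 0.0804). Casp14, a caspase of terminal differentiation, fell by 2.37 ± 0.16, and the heat shock gene Hspa1a by 2.30 ± 0.39.

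The clock kept running in MR knock out, with all 16 clock genes rhythmic (alone, 16, list adjusted p = 3.52e-10) and a mean shift of -0.94 h (SD 0.40, 14 genes, range -2.44 to 0.02). In level 11 clock genes fell and 1 rose (alone, 11 and 1, camera adjusted p = 0.0878). Per1 fell by 1.22 ± 0.10, Per2 by 0.79 ± 0.11 and Per3 by 0.63 ± 0.14. Of the clock genes 3 of 16 differed in rhythm (alone, 8, list adjusted p = 0.00438): Dbp (ZT10.5 against ZT11.8, adjusted p = 0.0068), Ciart (adjusted p = 9.56e-04) and Tef (adjusted p = 0.0282). Cell cycle genes differed in rhythm in 9 of 21 cases (alone, 18, list adjusted p = 1.09e-12), with Ccna2 peaking at ZT0.4 against ZT4.15 and Aurkb at ZT22.2 against ZT3.21.

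In total 7507 genes differed in level between MR knock out and wild type, 2813 higher and 4694 lower (37.5% higher). The share was 16.4% with FPKM as deposited, where the median of all genes was -0.24 against -0.08, and 48.3% with the length score as a covariate (4292 genes). Rhythmic genes numbered 2470, and 1626 without MR knock out ZT8 replicate 1. The 95 genes with a rhythm difference, Ccna2 among them, became 352 without MR knock out ZT12 replicate 1, 176 without MR knock out ZT16 replicate 1 and 143 without wild type ZT8 replicate 3, and ran from 0 without replicate number 2 in limma (482 genes at an unadjusted p under 0.05) to 6093 with array weights.

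The calls of both knock outs overlapped: 6055 genes moved in the same direction (2119 higher, 3936 lower) and 423 in opposite directions, Isg15 and Hsd11b2 among the former. Both comparisons share the wild-type libraries. Independent lists of these sizes would share 3185 genes. In 100 simulations of unchanged groups sharing a control 0 genes were shared, as limma called 0 for MR knock out, with no offset of all wild-type libraries simulated. At an unadjusted p under 0.05, 6329 were shared, against a simulated mean of 121 (highest 3476). Across genes, which are not independent replicates, the correlation of the log2 differences was 0.756, against a simulated mean of 0.505 (highest 0.9), and their covariance was 0.208 against 0.007 (highest 0.037). With 9 wild-type libraries for each knock out 3850 and 5393 were shared in the 2 ways of assignment. With the length score as a covariate 1483 were shared, and 382 with the low-scale libraries left out and cosine and sine terms as well.

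The low salt groups address how the time of feeding sets the colon's rhythms. The times of the clock moved: 15 of 16 clock genes differed in rhythm between day and night feeding (alone, 15, list adjusted p = 9.4e-05), with a mean shift of -9.23 h (SD 0.51, 14 genes, range -10.7 to -7). Nr1d1 peaked at ZT23.8 by day feeding and ZT9.59 by night feeding, Dbp at ZT2.69 and ZT12.3, Per2 at ZT6.86 and ZT17, and Arntl at ZT13.2 and ZT23.9. Cholesterol synthesis genes differed in 19 of 20 cases (alone, 20, list adjusted p = 5.11e-06) and fatty acid synthesis genes in 9 of 9 (alone, 9, list adjusted p = 0.00188). Dhcr7, the last enzyme of cholesterol synthesis, peaked at ZT6.41 against ZT17.7, Sqle at ZT4.44 against ZT17.9, Fasn, the fatty acid synthase, at ZT5.57 against ZT17.7, and Srebf1, their transcriptional regulator, at ZT7.37 against ZT19.3. Sodium uptake and aldosterone genes differed in 11 of 15 cases (alone, 11, list adjusted p = 0.0281), with Scnn1a at ZT5.67 against ZT13.7, Scnn1g at ZT7.41 against ZT13.4, Sgk1 at ZT8.14 against ZT15.2 and Hsd11b2 at ZT11.4 against ZT16.4. Glucocorticoid response genes (10 of 13, alone, 11, list adjusted p = 0.0281), fatty acid oxidation genes (14 of 20, alone, 14, list adjusted p = 0.0258), cell cycle genes (15 of 21, alone, 17, list adjusted p = 0.0211) and endoplasmic reticulum stress genes (11 of 14, alone, 12, list adjusted p = 0.0231) differed as well, and the chaperone Hspa5 was among the last (adjusted p = 0.00269).

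Mean levels of some defence and immune genes changed in the low salt groups. Ang4 rose by 2.92 ± 0.35 with day feeding (597 against 111 FPKM), Pnliprp2, a pancreatic lipase relative, by 2.54 ± 0.24 and Itln1 by 2.30 ± 0.28, each at 6 of 6 times. The goblet cell genes Retnlb, Clca1 and Spink4 rose by 1.87 ± 0.22, 0.93 ± 0.14 and 0.97 ± 0.17 (at 5, 6 and 5 of 6 times). All 5 T cell genes fell (alone, 5, camera adjusted p = 1.08e-07, adjusted p = 0.116 with an estimated correlation). Gzma, a granzyme of cytotoxic cells, was at -0.94 ± 0.21, Cd3e at -0.61 ± 0.13 and Cd8a at -0.54 ± 0.11. Interferon response genes fell in 5 of 14 cases (alone, 11, camera adjusted p = 2.94e-08, adjusted p = 0.37 with an estimated correlation). Iigp1 fell by 1.24 ± 0.27, Ifi27l2a by 1.04 ± 0.24, Ifi44 by 0.74 ± 0.13 and Ifit1 by 0.60 ± 0.13. Of the sodium uptake and aldosterone genes, Hsd11b2 fell by 0.23 ± 0.06 and Kcnma1, a potassium channel, by 0.30 ± 0.09 (lower at 3 and 5 of 6 times). Scnn1a (0.12 ± 0.09), Scnn1b (-0.10 ± 0.10), Scnn1g (0.09 ± 0.14), Sgk1 (0.15 ± 0.18) and Nr3c2 (-0.14 ± 0.15) did not pass. The cholesterol synthesis, cell cycle, MHC class II and inflammatory lists passed camera (adjusted p = 0.0346, 0.00297, 0.0276 and 0.0458) with 1, 0, 0 and 1 members passing limma's test (alone, 2, 0, 0 and 1). An unadjusted p under 0.05 was seen for 5 cell cycle and 5 MHC class II genes, and all 4 lists stood at adjusted p = 0.799 with an estimated correlation. The MHC class II and inflammatory calls ended with array weights (adjusted p = 0.542 and 0.195) and the cholesterol synthesis call with FPKM as deposited (0.0596).

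Day and night feeding differed in the level of 379 genes under low salt, 118 higher and 261 lower (31.1% higher, 43% with quantile normalization and 49.4% with FPKM as deposited), and in the rhythm of 4388, Nr1d1 among them. The level count was 228 without low salt night fed ZT8 replicate 1, 601 without low salt night fed ZT8 replicate 3, 606 without low salt night fed ZT0 replicate 2, 246 without low salt night fed ZT12 replicate 3, 243 without low salt day fed ZT12 replicate 2 and 240 without low salt day fed ZT16 replicate 2. Over the alternatives it ran from 47 without replicate number 1 to 5348 with array weights. Rhythmic genes numbered 2573 by night and 4798 by day feeding, and 2999 of the latter without low salt day fed ZT16 replicate 2. Of 1011 genes rhythmic in both groups 69.8% had peaks more than 6 h apart.

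Under high salt, 15 of 16 clock genes also differed in rhythm between day and night feeding (alone, 15, list adjusted p = 1.53e-05), with a mean shift of -5.74 h (SD 1.17, 14 genes) and single genes spread from -11.7 to 11.3 h. Per2 peaked at ZT4.59 against ZT17.3, but Dbp at ZT9.72 against ZT12.3 and Arntl at ZT22.2 against ZT0.56. In the libraries labelled high salt day fed, Nr1d1 stood at 1.47 ± 0.447 FPKM (SD, n = 3) at ZT0 and 30.5 ± 1.67 at ZT12, close to 1.55 and 32.8 in high salt night fed, whereas its levels at ZT4, ZT8, ZT16 and ZT20 were 9.72, 1.63, 11.6 and 25.8. With cosine and sine terms the mean shift was -7.26 h, and with these terms and without ZT0 and ZT12 of high salt day fed, both chosen after seeing the data, -11.6 h. Cholesterol synthesis genes differed in rhythm in 17 of 20 cases (alone, 17, list adjusted p = 2.75e-05), fatty acid synthesis genes in 9 of 9 (alone, 9, list adjusted p = 2.38e-04) and endoplasmic reticulum stress genes in 13 of 14 (alone, 14, list adjusted p = 4.27e-05). The desaturase Scd2 peaked at ZT3.69 against ZT20.5, Dhcr7 at ZT4.74 against ZT19.7 and Hspa5 at ZT1.92 against ZT20.7. Cell cycle genes differed in 17 of 21 cases (alone, 19, list adjusted p = 5.02e-05), sodium uptake and aldosterone genes in 11 of 15 (alone, 11, list adjusted p = 0.00599) and MHC class II genes in 7 of 7 (alone, 7, list adjusted p = 0.00189).

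Under high salt, interferon response, MHC class II and T cell genes were higher with day feeding. All 14 interferon response genes rose (alone, 14; mean log2 2.05, camera adjusted p = 2.94e-42, adjusted p = 9.22e-05 with an estimated correlation), Isg15 by 3.12 ± 0.15 (95.9 against 11.1 FPKM), Oasl2 by 2.94 ± 0.12 and Ifi27l2a by 3.51 ± 0.24. All 7 MHC class II genes (alone, 7, camera adjusted p = 1.16e-11) and all 5 T cell genes (alone, 5, camera adjusted p = 1.06e-07) rose, each at adjusted p = 0.0424 with an estimated correlation, with Cd74 up by 2.49 ± 0.26, H2-Ab1 by 1.95 ± 0.21, Gzma by 2.01 ± 0.21 and Cd8a by 0.97 ± 0.11. Immediate early genes fell in 5 of 10 cases (alone, 6, camera adjusted p = 0.000402, adjusted p = 0.653 with an estimated correlation), with a mean of 0.06 with FPKM as deposited. Nr4a1 fell by 1.08 ± 0.18, Arc by 0.97 ± 0.12, the growth factor Areg by 0.75 ± 0.11 and Fxyd4 by 1.15 ± 0.22, each at 6 of 6 times. Ribosomal protein genes fell in 12 of 15 cases (alone, 14, camera adjusted p = 5.63e-06, adjusted p = 0.653 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.154) and whose mean was 0.18 with FPKM as deposited. Rpl8 fell by 0.40 ± 0.11 and Rps6 by 0.27 ± 0.08, each at 5 of 6 times. Fatty acid oxidation genes rose in 6 of 20 cases (alone, 6, camera adjusted p = 0.0364, adjusted p = 0.664 with an estimated correlation), a call that ended with array weights (adjusted p = 0.273). Of the sodium uptake and aldosterone genes 4 rose (alone, 5 and 2 falls; camera adjusted p = 0.363), among them Atp1b1 by 0.22 ± 0.07, Hsd11b2 by 0.23 ± 0.06 and Fkbp5 by 0.27 ± 0.08 (each higher at 4 of 6 times). Scnn1a (0.03 ± 0.09), Scnn1b (-0.24 ± 0.10), Scnn1g (-0.06 ± 0.14), Sgk1 (0.20 ± 0.18) and Nr3c2 (0.25 ± 0.15) did not pass.

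Day and night feeding differed in the level of 3135 genes under high salt, 1672 higher and 1463 lower (53.3% higher), and in the rhythm of 3692. All genes had a median of 0.02, and 0.41 with FPKM as deposited, where 9984 genes were called and 99.5% were higher. With cosine and sine terms 2761 genes differed in level and 3161 in rhythm, and without the 5 low-scale libraries of high salt night fed, at ZT8 and ZT12, as well 806 (74.3% higher) and 1549. Rhythmic genes numbered 6490 by night feeding, 6128 with these terms and 866 with both changes. They numbered 3599 by day feeding, where the count was 2139 without high salt day fed ZT0 replicate 1, 2338 without ZT0 replicate 3, 2265 without ZT4 replicate 1, 1824 without ZT16 replicate 1, 3128 with cosine and sine terms and 547 with these terms and without ZT0 and ZT12; Per2 was among them.

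High against low salt at night asks how salt load acts at the usual mealtime. Sodium uptake and aldosterone genes fell in 10 of 15 cases (alone, 11, camera adjusted p = 1.47e-08, adjusted p = 0.00855 with an estimated correlation). Hsd11b2 fell by 1.08 ± 0.06 (75.1 against 156 FPKM), Scnn1g by 1.36 ± 0.14 (0.124 against 1.43 FPKM), Scnn1b by 0.87 ± 0.10, Sgk1 by 0.83 ± 0.18, Fkbp5 by 0.69 ± 0.08 and Scnn1a by 0.44 ± 0.09. Scnn1b and Sgk1 were lower at 5 of 6 times and the other 4 at all 6, and Nr3c2 did not pass (-0.31 ± 0.15, adjusted p = 0.103). Best2 fell by 1.74 ± 0.14, and Fxyd4, looked up after its values in the other comparisons were seen, by 2.1 ± 0.22 (29 against 122 FPKM). The rhythm of Scnn1b peaked at ZT7.99 against ZT14.1 (adjusted p = 0.00282) and that of Hsd11b2 at ZT19.5 against ZT16.4 (adjusted p = 5.57e-04).

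**Figure D3:**
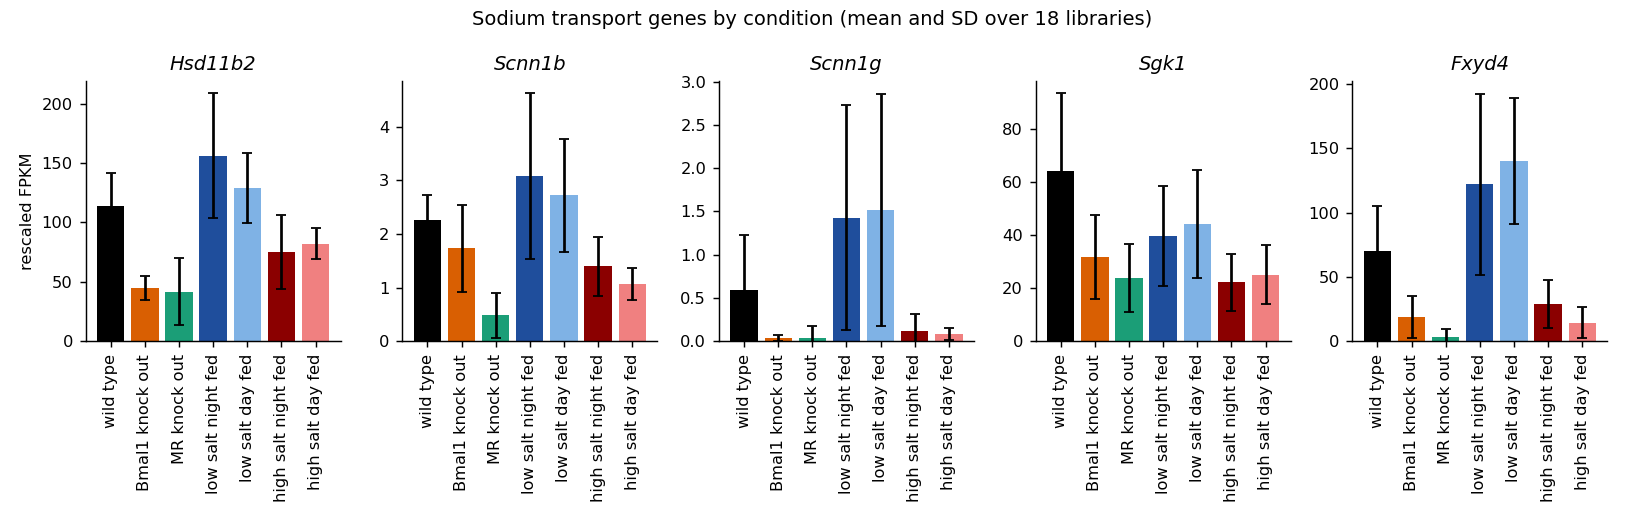
Rescaled FPKM of Hsd11b2, Scnn1b, Scnn1g, Sgk1 and Fxyd4 in the 7 conditions (means with SD over 18 libraries, 3 at each of 6 times). Hsd11b2 stands at 156 in low salt night fed, 129 in low salt day fed, 75.1 in high salt night fed and 82.2 in high salt day fed.

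Interferon response, MHC class II and T cell genes were lower under high salt at night. All 14 interferon response genes fell (alone, 14, camera adjusted p = 1.02e-30, adjusted p = 0.00133 with an estimated correlation), Isg15 by 2.77 ± 0.15 (11.1 against 84.4 FPKM), Oasl2 by 2.76 ± 0.12 and Ifi27l2a by 3.30 ± 0.24. All 5 T cell genes fell (alone, 5, camera adjusted p = 3.17e-09, adjusted p = 0.0165 with an estimated correlation). Gzma was at -2.29 ± 0.21 and Cd8a at -1.23 ± 0.11. MHC class II genes fell in 7 of 7 cases (alone, 7, camera adjusted p = 0.000454, adjusted p = 0.535 with an estimated correlation), a call that ended with FPKM as deposited (adjusted p = 0.108). Cd74 was at -1.55 ± 0.26 and H2-Eb1 at -1.10 ± 0.19 (each lower at 4 of 6 times). Among the rises were Akr1c18, a steroid reductase, by 1.16 ± 0.11, Cma1, a mast cell protease, by 1.16 ± 0.13, and the lysozyme Lyz1 by 0.98 ± 0.16. Ribosomal protein genes rose in 8 of 15 cases (alone, 10, camera adjusted p = 0.000894, adjusted p = 0.946 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.7) and whose mean turned to -0.28 with FPKM as deposited. Rps19 rose by 0.55 ± 0.15 and Rpl8 by 0.33 ± 0.11. Cell cycle genes rose in 4 of 21 cases (alone, 3, camera adjusted p = 0.006, adjusted p = 0.946 with an estimated correlation), with a mean of -0.29 with FPKM as deposited.

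The clock was in place at both salt levels. In limma 0 of 16 clock genes differed in rhythm (3 at an unadjusted p under 0.05), and the mean shift was 0.21 h (SD 0.66, 15 genes, range -1.18 to 1.19). Nr1d1 peaked at ZT9.46 against ZT9.59, Dbp at ZT12.3 in both and Per2 at ZT17.3 against ZT17. In level 4 clock genes fell and 1 rose (alone, 4 and 1, camera adjusted p = 0.353). Per1 was at -0.34 ± 0.08, Arntl at -0.28 ± 0.10 and Per3 at -0.27 ± 0.08, with Nfil3 up by 0.27 ± 0.09 (-0.14 with FPKM as deposited). Interferon response genes differed in rhythm in 7 of 14 cases (alone, 10, list adjusted p = 0.00978) and MHC class II genes in 6 of 7 (alone, 6, list adjusted p = 6.41e-04), with Cd74 peaking at ZT18.3 against ZT3.18. Of all genes 2 differed in rhythm with cosine and sine terms and without the low-scale libraries, so all but at most 2 of the rhythm differences named for this comparison ended in that setting.

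Night-fed mice on high and low salt differed in the level of 3978 genes, 1752 higher and 2226 lower (44% higher), and in the rhythm of 1398, Cd74 among them. The median of all genes was -0.03, and -0.45 with FPKM as deposited, where 0.7% of 9988 calls were higher. With cosine and sine terms 3599 genes differed in level and 947 in rhythm, and with these terms and without the 5 low-scale libraries of high salt night fed 1546 (33.9% higher) and 2. The rhythm count was 567 without low salt night fed ZT0 replicate 2, 787 without low salt night fed ZT12 replicate 3, 750 without high salt night fed ZT0 replicate 2, 2458 without high salt night fed ZT12 replicate 1, 762 without ZT12 replicate 2 and 733 without ZT12 replicate 3, and 0 in limma without replicate number 2 (1125 genes at an unadjusted p under 0.05).

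High against low salt by day asks the same at the inverted mealtime. Sodium uptake and aldosterone genes fell in 7 of 15 cases with 1 rise (alone, 9 and 2, camera adjusted p = 1.46e-07, adjusted p = 0.0346 with an estimated correlation). Scnn1g fell by 1.52 ± 0.14 (0.0841 against 1.52 FPKM), Scnn1b by 1.01 ± 0.10, Sgk1 by 0.78 ± 0.18, Hsd11b2 by 0.63 ± 0.06, Scnn1a by 0.53 ± 0.09 and Fkbp5 by 0.49 ± 0.08. Hsd11b2 was lower at 5 of 6 times and the other 5 at all 6, and Nr3c2 did not pass (0.09 ± 0.15, adjusted p = 0.752). Fxyd4 had the largest fall, by 3.61 ± 0.22 (14.5 against 140 FPKM), and Best2 fell by 1.46 ± 0.14. Glucocorticoid response genes fell in 7 of 13 cases (alone, 8 and 1 rise; camera adjusted p = 0.000556, adjusted p = 0.0549 with an estimated correlation). Tsc22d3, a glucocorticoid-induced leucine zipper protein, was at -0.37 ± 0.07 and the metallothionein Mt1 at -0.48 ± 0.11 (lower at 5 and 3 of 6 times). The distal colon markers Hoxb13 and Hoxd13 fell by 0.66 ± 0.09 and by 0.61 ± 0.12, as did all 4 genes of that list (alone, 4, camera adjusted p = 8.76e-06, adjusted p = 0.0549 with an estimated correlation).

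Interferon response genes rose in 13 of 14 cases under high salt by day (alone, 13, camera adjusted p = 1.05e-13, adjusted p = 0.0549 with an estimated correlation). Ifi44 rose by 1.34 ± 0.13 and Ifit2 by 1.31 ± 0.16. All 7 MHC class II genes rose (alone, 7, camera adjusted p = 9.94e-10, adjusted p = 0.0549 with an estimated correlation). Cd74 rose by 1.52 ± 0.26 and H2-Ab1 by 1.34 ± 0.21. Reg3g and Reg3b rose by 1.92 ± 0.40 and 1.32 ± 0.40, and the nitric oxide synthase Nos2 by 1.62 ± 0.26. The secreted defence genes Ang4, Itln1 and Retnlb fell by 3.05 ± 0.35, by 1.77 ± 0.28 and by 1.57 ± 0.22. Goblet cell genes fell in 5 of 9 cases with 1 rise (alone, 5 and 1, camera adjusted p = 0.0172, adjusted p = 0.521 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.0762). Clca1, Spink4 and Tff3 were at -1.39 ± 0.14, -0.77 ± 0.17 and -0.50 ± 0.13, and the lineage factor Atoh1 rose by 0.40 ± 0.09. Of 16 clock genes 6 fell and 0 rose (alone, 6, camera adjusted p = 0.00534, adjusted p = 0.354 with an estimated correlation). Per1 was at -0.43 ± 0.08, Arntl at -0.40 ± 0.10 and Nr1d1 at -0.30 ± 0.10. The xenobiotic (5 higher, 2 lower), immediate early (4 lower), cell cycle (1 higher) and ribosomal protein lists (1 lower) passed camera (adjusted p = 0.0186, 0.0172, 0.00534 and 0.0172) and were at adjusted p = 0.521, 0.564, 0.621 and 0.621 with an estimated correlation. The immediate early and ribosomal protein calls ended with quantile normalization (adjusted p = 0.0762 and 0.207), the xenobiotic call with array weights (0.154) and the cell cycle call without replicate number 2 (0.0779).

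**Figure D4:**
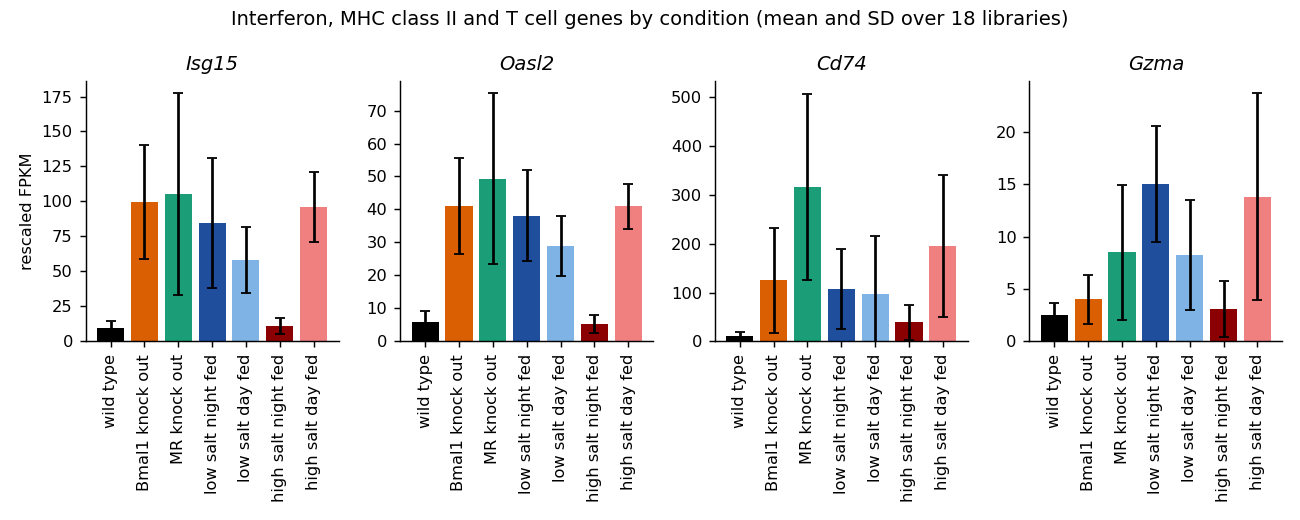
Rescaled FPKM of Isg15, Oasl2, Cd74 and Gzma in the 7 conditions (means with SD over 18 libraries, 3 at each of 6 times). Isg15 is lowest in wild type (9.53) and high salt night fed (11.1) and stands between 58.1 and 105 in the other conditions.

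In rhythm 13 of 16 clock genes differed between high and low salt by day (alone, 13, list adjusted p = 5.58e-09), with a mean shift of 4.53 h (SD 1.27, 13 genes, range -8.13 to 8.94) that was 2.55 h without replicate number 1, 1.67 h with cosine and sine terms and -2.05 h with these terms and without ZT0 and ZT12 of high salt day fed. Nr1d1 peaked at ZT15.7 against ZT23.8 and Dbp at ZT9.72 against ZT2.69. Heat shock genes differed in 9 of 12 cases (alone, 10, list adjusted p = 3.5e-06), endoplasmic reticulum stress genes in 11 of 14 (alone, 11, list adjusted p = 1.45e-07), MHC class II genes in 7 of 7 (alone, 7, list adjusted p = 2.31e-06) and goblet cell genes in 7 of 9 (alone, 8, list adjusted p = 4.06e-05). The chaperone Hspa8 peaked at ZT3.55 against ZT11.8, Cd74 at ZT0.82 against ZT11.5 and Hsd11b2 at ZT1.63 against ZT11.4. In all, 1688 genes differed in level, 886 higher and 802 lower (52.5% higher, 25.5% with FPKM as deposited), and 1285 in rhythm. The rhythm count was 802 with cosine and sine terms and 129 with these terms and without ZT0 and ZT12 of high salt day fed. The level count ran from 579 without replicate number 3 to 5306 with array weights.

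Whether the salt effect depended on feeding time was tested as an interaction, the day-fed minus the night-fed salt difference. Interferon response genes were higher in 13 of 14 cases (alone, 14; mean log2 2.43, camera adjusted p = 4.24e-40, adjusted p = 1.49e-04 with an estimated correlation), for example Isg15 at 3.54 ± 0.22 and Oasl2 at 3.30 ± 0.17. The calls between salt levels pointed down at night (14 of 14) and up by day (13 of 14). All 7 MHC class II genes (alone, 7, camera adjusted p = 6.82e-11, adjusted p = 0.0433 with an estimated correlation) and all 5 T cell genes (alone, 5, camera adjusted p = 2.56e-10, adjusted p = 0.0151 with an estimated correlation) were higher too, with Cd74 at 3.07 ± 0.36 and Gzma at 2.95 ± 0.30. Ang4 was lower, at -3.80 ± 0.50, and Fxyd4 at -1.51 ± 0.31. Sodium uptake and aldosterone genes passed in 4 of 15 cases, all higher (alone, 4, camera adjusted p = 0.189, adjusted p = 0.689 with an estimated correlation). Hsd11b2 was at 0.45 ± 0.08, while Scnn1a (-0.09 ± 0.12), Scnn1b (-0.14 ± 0.14), Scnn1g (-0.15 ± 0.20), Sgk1 (0.05 ± 0.25) and Nr3c2 (0.40 ± 0.21) did not pass. Ribosomal protein (8 of 15 lower, alone, 12, camera adjusted p = 8.44e-06) and immediate early genes (4 of 10 lower, alone, 4, camera adjusted p = 0.03) were at adjusted p = 0.689 with an estimated correlation. Both calls ended with quantile normalization (adjusted p = 0.228 and 0.176), and both means were positive with FPKM as deposited (0.11 and 0.10). Clock genes differed in rhythm in 11 of 16 cases (alone, 11, list adjusted p = 4.87e-09), Nr1d1 with adjusted p = 5.09e-12, and MHC class II genes in 6 of 7 (alone, 7, list adjusted p = 5.61e-06).

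In total the interaction passed for the level of 2245 genes, 1250 higher and 995 lower (55.7% higher), and for the rhythm of 707. The share higher was 99% with FPKM as deposited, 44.6% with quantile normalization, 57% with cosine and sine terms (1847 genes) and 80.7% with these terms and without the low-scale libraries (508 genes). The median of all genes was 0.04, and 0.42 with FPKM as deposited. The level count was 488 and 460 without replicate numbers 1 and 3 and 3447 without low salt night fed ZT0 replicate 2. The rhythm count was 1233 without high salt night fed ZT12 replicate 1 and 321 with cosine and sine terms, and with these terms 108 without the low-scale libraries and 58 without ZT0 and ZT12 of high salt day fed, Nr1d1 being among the genes called with all libraries.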

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

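In this part the tests on exchanged times, libraries of high salt night fed animals and chromosome 7 were set out before their results. Those on scale factor, transcript length, mapped reads and libraries of low salt night fed animals were chosen only after the results were seen.

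Listed first are salt effects that differed by feeding time in the interaction test (day-fed minus night-fed salt difference, log2). It passed for the level of 2245 genes (19.7%) and the rhythm of 707. Of the 62 named partly for changes in the feeding comparisons, which raises the share, 34 passed for level. Interferon response and interferon-induced genes were higher: Isg15 3.54, Oasl2 3.30, Ifi27l2a 4.55, Ifi44 3.77, Ifit1 3.17, Ifit2 3.49 and Iigp1 3.17. MHC class II and T cell genes were too: Cd74 3.07, H2-Ab1 2.37, H2-Eb1 2.24, Gzma 2.95, Cd3e 1.40 and Cd8a 1.51. Nos2 was at 2.02. Of the transport and lineage genes, Hsd11b2 was at 0.45, Atp1b1 at 0.40, Kcnma1 at 0.35, Atoh1 at 0.43 and Srebf1 at 0.22. Lower were Ang4 -3.80, Itln1 -2.77, Retnlb -1.88, Clca1 -1.45, Spink4 -1.63, Lyz1 -0.82 and Pnliprp2 -3.14. Also lower were Fxyd4 -1.51, Nr4a1 -1.18, Arc -0.98, Areg -0.87, Mt1 -0.52, Nfil3 -0.35, Rpl8 -0.50 and Rps6 -0.37.

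Bmal1 knock out and high salt night fed had the most rhythmic genes of the 7 conditions, 6450 and 6490, and held the 14 libraries of low scale factor. The tables argue against fewer mapped reads, whose relative number had a median of 1.187 in these libraries and 1.195 in the others (reads on genes were fewer, with medians of 0.472 and 1.348), and against transcript length as the whole cause, since 5473 and 5656 genes, still the most of the 7 conditions, were called with the length score as a covariate, though wild type and low salt night fed rose from 2011 and 2573 to 4247 and 4191, so a part of length in the excess over them stays open. In high salt night fed 13.7% of the calls with cosine and sine terms were kept without its 5 low-scale libraries, against 66.6% in low salt night fed and 75.4% in low salt day fed without the same times and replicate numbers, so low yield at ZT8 and ZT12 may account for much of that count. In Bmal1 knock out 11.6% were kept without 9 libraries, and wild type and MR knock out kept 5% and 4.8%; the bound set for this test, a share at least as large as in these controls, was wrong, because controls that lose nearly all calls cannot lie above it, so low yield cannot be told apart from a change of rhythm there. Genotype and diet, the biological differences in the design, stay open and untested.

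In high salt day fed the clock genes Nr1d1 and Arntl stood at ZT0 and ZT12 close to night-fed values. An exchange of these times would turn the ZT0 minus ZT12 difference against that of low salt day fed, but outside the clock list (4783 genes, not independent replicates) the correlation was 0.263, against 0.555 for both other pairs of opposite times; with high and low salt night fed it was 0.771 and 0.623, against -0.431 and -0.636 for ZT4 minus ZT16 and -0.478 and -0.469 for ZT8 minus ZT20. The 0.263 met the bound set beforehand against an exchange (above 0.2). Its margin is below the spread over replicate numbers (0.249, -0.38 and 0.401), which that bound left out. An exchange thus cannot be told apart from a response of the clock to salt by day, which is untested. Libraries of high salt night fed animals are argued against by the interferon response list, whose mean log2 level was 4.319 ± 0.097 (SD, n = 6) at ZT0 and ZT12, 4.093 ± 0.264 (n = 12) at the group's other times and 1.997 ± 0.214 (n = 6) in high salt night fed at ZT0 and ZT12. For the sodium uptake and aldosterone list these levels were 4.093 ± 0.092 and 3.967 ± 0.194. It was at 4.451 ± 0.392 in low salt night fed at ZT0 and ZT12, a gap within that SD. This bound was added once the values were seen. The SD pools both times of a list rhythmic there (11 of 15 genes), so the gap decides neither way. At the other times 30 genes differed from low salt night fed by a log2 beyond 1 (median 1.376). At ZT0 and ZT12 their median was 0.567 ± 0.186 (SD over replicate numbers). There limma called 3 genes, and Fxyd4 was at 3.01 and 30.2 against 71.1 and 140 FPKM. Libraries of low salt night fed animals thus cannot be told apart from the group's own either, and no label was changed.

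Hddc3 and Trim12a, among the largest changes in Bmal1 knock out, lie on chromosome 7 with Arntl, at -32.9 and -9 Mb from it, so a segment of another strain carried along with the targeted gene is a candidate explanation. Of 313 genes changed beyond a log2 of 1 in Bmal1 knock out and near 0 in MR knock out, 19 lay within 40 Mb of Arntl (6.1% against 3.9% of other genes, odds ratio 1.606, Fisher's exact p = 0.0544), and without Hddc3, the 1 of the pair among the 313 (Trim12a rose by 1.03 in MR knock out), the ratio was 1.525 (Fisher's exact p = 0.101). For 48 genes changed in the same way in MR knock out alone, the ratio within that window was 1.634 (3 genes, Fisher's exact p = 0.437). These values decide neither way, so a strain segment cannot be told apart from an effect of the lost clock, which is untested.

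The samples were also split into groups of the same sizes in 100 ways, the real one included. For the rhythmic genes as many were called in 1 split in wild type (2011, highest other 108), 1 in Bmal1 knock out (6450, 4443), 2 in MR knock out (2470, 4125), 3 in low salt night fed (2573, 3258), 1 in low salt day fed (4798, 1907), 1 in high salt night fed (6490, 4663) and 2 in high salt day fed (3599, 4621). For levels 1 split of 100, the real one, gave as many in Bmal1 knock out (9135, 6981), MR knock out (7507, 5345), low salt day against night (379, 313), high salt day against night (3135, 3103), night high against low salt (3978, 2165), day high against low salt (1688, 43) and the interaction (2245, 4). For rhythm differences the share was under 0.05 for low salt day against night (1 split, 4388, highest other 1778), high salt day against night (2 splits, 3692, 4029), day high against low salt (1 split, 1285, 68) and the interaction (1 split, 707, 14). It was 0.05 or more for Bmal1 knock out (5 splits, 3546, 7810), MR knock out (6 splits, 95, 4855) and night high against low salt (5 splits, 1398, 3841). The MR knock out split with 4855 genes points to an untested structure of the samples. Shares were not corrected over results. Relabelling moves real effects, such as salt for the interaction, into the residuals, so low shares do not exclude chance.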

How the results depend on the processing

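The settings with the length score, the cosine and sine terms, the libraries of low scale factor left out and the times left out were chosen only after the results were seen, and the others before. Of the main values under other settings, 388 stayed within 1.5 times, 173 moved further and 1 call, that of Arntl, ended. Quantile normalization, no filter on low values and a pseudocount of 0.1 moved no count, shift or targeted gene by these limits. Where a value moved, the cause was not tested. Of 209 values of named genes, 178 had the same call with FPKM as deposited, 197 with the length score, 195 with cosine and sine terms and without low-scale libraries and 176 with the length score as well.

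With FPKM as deposited rhythmic genes numbered 375 in wild type, 10842 in Bmal1 knock out, 941 in MR knock out, 1035 in low salt night fed, 2696 in low salt day fed and 10380 in high salt night fed. Rhythm differences were 9911 for Bmal1 knock out, 7 for MR knock out, 2109 for low salt day against night, 9868 for high salt day against night, 9579 for night high against low salt, 2945 for day high against low salt and 7132 for the interaction. Level differences were 79 for low salt day against night, 9984 for high salt day against night, 9988 for night high against low salt, 1049 for day high against low salt and 8402 for the interaction. The clock shift was -10.45 h in Bmal1 knock out and 1.17 h for night high against low salt.

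With array weights rhythmic genes numbered 7444 in wild type, 8014 in MR knock out, 9225 in low salt night fed, 8861 in low salt day fed and 9598 in high salt day fed. Rhythm differences were 6970 for Bmal1 knock out, 6093 for MR knock out, 9505 for low salt day against night, 8373 for high salt day against night, 6068 for night high against low salt, 8503 for day high against low salt and 7275 for the interaction. Level differences were 5348, 6575, 7523, 5306 and 7347 for the last 5 of these. The day-fed clock shift between salt levels was 2.47 h, and 12 list tests of rhythm passed.

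Other fixed settings moved fewer values. A pseudocount of 1 gave a Bmal1 knock out clock shift of 3.79 h. With genes at a mean FPKM of 5 or more, MR knock out had 1594 rhythmic genes, 4985 level differences and 47 rhythm differences, and 4013 calls were shared by the knock outs. Fits of the 18 libraries of a condition alone gave 3296 rhythmic genes in wild type, 759 in MR knock out, 1679 in low salt night fed and 1250 in high salt day fed. A fit of the 36 compared libraries gave 538 rhythm differences for night high against low salt. Time as a factor gave 1245 rhythmic genes in wild type and rhythm differences of 2094 for Bmal1 knock out, 63 for MR knock out and 708 for day high against low salt.

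With the length score as a covariate rhythmic genes numbered 4247 in wild type, 4191 in low salt night fed, 2870 in low salt day fed and 2268 in high salt day fed. Level differences were 4087 for Bmal1 knock out, 4292 for MR knock out, 1341 for low salt day against night and 3411 for day high against low salt. Rhythm differences were 369 for MR knock out, 2180 for night high against low salt, 3297 for day high against low salt and 2726 for the interaction, and 1483 calls were shared by the knock outs.

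With cosine and sine terms MR knock out had 59 rhythm differences, low salt day against night 239 level differences, day high against low salt 802 rhythm differences and the interaction 321. Clock shifts were 3.8 h in Bmal1 knock out, -7.26 h for high salt day against night and 1.67 h for day high against low salt.

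Without the libraries of low scale factor, with the same terms, rhythmic genes numbered 754 in Bmal1 knock out and 866 in high salt night fed. Rhythm differences were 279 for Bmal1 knock out, 51 for MR knock out, 1549 for high salt day against night, 2 for night high against low salt and 108 for the interaction. Level differences were 806 for high salt day against night, 1546 for night high against low salt and 508 for the interaction. Clock shifts were -8.91 h for high salt day against night and 1.67 h for day high against low salt.

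Without these libraries and with the length score, rhythmic genes numbered 4097 in wild type, 176 in Bmal1 knock out, 1990 in low salt day fed, 1547 in high salt night fed and 2033 in high salt day fed. Level differences were 892 for Bmal1 knock out, 4286 for MR knock out, 1052 for low salt day against night, 1347 for high salt day against night, 2370 for night high against low salt, 3035 for day high against low salt and 642 for the interaction. Rhythm differences were 244 for Bmal1 knock out, 199 for MR knock out, 3 for night high against low salt, 2524 for day high against low salt and 442 for the interaction. Clock shifts were -8.6 h for high salt day against night and 1.78 h for day high against low salt, 382 calls were shared by the knock outs, and Arntl was at -0.277.

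Without ZT0 and ZT12 of high salt day fed, with the same terms, 547 genes were rhythmic in that group, against 3128 with the terms alone. High salt day against night had 1685 level differences and a clock shift of -11.6 h, day high against low salt 129 rhythm differences and a shift of -2.05 h, and the interaction 1304 level and 58 rhythm differences.

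Leaving out each replicate number gave these ranges. Rhythmic genes ran from 704 to 1536 in wild type, 2316 to 6377 in Bmal1 knock out, 337 to 1475 in MR knock out, 988 to 1165 in low salt night fed, 869 to 2271 in low salt day fed, 3861 to 5901 in high salt night fed and 371 to 3998 in high salt day fed. Level differences ran from 4978 to 7562 for MR knock out, 47 to 52 for low salt day against night, 831 to 3448 for high salt day against night, 1662 to 3375 for night high against low salt, 579 to 1076 for day high against low salt and 460 to 3441 for the interaction. Rhythm differences ran from 376 to 2774 for Bmal1 knock out, 0 to 134 for MR knock out, 1503 to 2555 for low salt day against night, 2137 to 2411 for high salt day against night, 0 to 1868 for night high against low salt, 403 to 470 for day high against low salt and 119 to 583 for the interaction. The counts of 0 are from limma, where 482 and 1125 genes had an unadjusted p under 0.05. Clock shifts ran from 0.29 to 5.93 h in Bmal1 knock out, -0.15 to 0.4 h for night high against low salt and 2.55 to 4.32 h for day high against low salt, and 3912 to 6033 calls were shared by the knock outs.

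Leaving out single libraries moved some counts further than 1.5 times. MR knock out had 1626 rhythmic genes without its ZT8 replicate 1 and 352 rhythm differences without its ZT12 replicate 1. Low salt day against night had 228 level differences without low salt night fed ZT8 replicate 1 and 606 without low salt night fed ZT0 replicate 2, and low salt day fed had 2999 rhythmic genes without its ZT16 replicate 2. High salt day fed had 1824 rhythmic genes without its ZT16 replicate 1. Night high against low salt had 567 rhythm differences without low salt night fed ZT0 replicate 2 and 2458 without high salt night fed ZT12 replicate 1. The interaction had 3447 level differences without the former library and 1233 rhythm differences without the latter. The highest counts without 1 library that stayed within 1.5 times were, for rhythmic genes, 2171 in wild type, 7044 in Bmal1 knock out, 2970 in MR knock out, 3164 in low salt night fed, 4990 in low salt day fed, 7266 in high salt night fed and 5229 in high salt day fed. For levels they were 7982 for MR knock out, 4025 for high salt day against night, 4875 for night high against low salt and 2054 for day high against low salt, and for rhythm differences 4673 for Bmal1 knock out, 5387 for low salt day against night, 4374 for high salt day against night and 1529 for day high against low salt.

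Some directions turned. With FPKM as deposited, Bmal1 knock out minus wild type turned to -0.026 for Npas2, -0.297 for Aurka and -0.102 for Rpl8. High salt day against night turned to 0.055 for Rpl8 and 0.184 for Rps6, and night high against low salt to -0.165 for Rpl8 and -0.14 for Nfil3. With the length score, Bmal1 knock out turned to 0.037 for Per2 and 0.185 for Clock, and with low-scale libraries left out as well to 0.234 for Clock. The mean of the ribosomal protein list in Bmal1 knock out turned to -0.08 with quantile normalization, -0.069 with the length score and -0.033 with low-scale libraries left out as well.

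Of 55 camera calls of gene lists, 14 ended with array weights, 9 with FPKM as deposited, 9 with quantile normalization and 6 with the length score beside 1 that also turned in each, 4 with a pseudocount of 0.1, 1 with a pseudocount of 1, 2 with genes at a mean FPKM of 5 or more (of 46), 0 with no filter on low values, and 5, 7 and 12 without replicate numbers 1, 2 and 3. Cosine and sine terms ended 2, these terms without low-scale libraries 4, with the length score as well 9 beside 1 that also turned, and without ZT0 and ZT12 of high salt day fed 2 of 22. With the lowest and highest adjusted p of the settings that ended them, other than the replicate block, these were in Bmal1 knock out ribosomal protein, the list that turned (0.164 and 0.414), sodium uptake and aldosterone (0.0562), cell cycle (0.0653) and fatty acid oxidation (0.0516 and 0.143). In MR knock out these were cholesterol synthesis (0.0548 and 0.245), crypt base (0.0563 and 0.0922), enteroendocrine (0.0513 and 0.103), T cell (0.0548 and 0.124), cell cycle (0.0679 and 0.103), surface colonocyte (0.134) and distal colon Hox (0.074). For low salt day against night they were MHC class II (0.0528 and 0.575), cholesterol synthesis (0.0596 and 0.189) and inflammatory (0.0683 and 0.195), and for high salt day against night fatty acid oxidation (0.067 and 0.375), ribosomal protein (0.154) and immediate early (0.0951). For night high against low salt they were MHC class II (0.108), ribosomal protein (0.273 and 0.7) and cell cycle (0.104). For day high against low salt they were immediate early (0.0553 and 0.212), ribosomal protein (0.098 and 0.509), goblet cell (0.05 and 0.108), xenobiotic metabolism (0.136 and 0.154), cell cycle (0.0779) and core clock (0.0553), and for the interaction immediate early (0.176 and 0.735) and ribosomal protein (0.228).

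Replicate numbers do not pair libraries across conditions: over 18 pairs per comparison the mean correlation of residuals with the same number ran from -0.146 to 0.055. A replicate block moved none of the 32 main values by over 1.5 times, but under the block 4 camera calls of MR knock out ended: cholesterol synthesis (adjusted p = 0.0525), crypt base and stem cell (0.0563), enteroendocrine cell (0.0522) and T cell (0.0517).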

Other observations

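Tests of the timing of gene groups here were planned except those with cosine and sine terms. Levels of Isg15 across the 7 conditions carry no test. Isg15 had a mean of 9.53 ± 5.17 FPKM (SD, n = 18) in wild type and 11.1 ± 5.74 in high salt night fed, against 99.8 ± 40.8 in Bmal1 knock out, 105 ± 72.2 in MR knock out, 84.4 ± 46.6 in low salt night fed, 58.1 ± 23.3 in low salt day fed and 95.9 ± 24.9 in high salt day fed.

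Cholesterol synthesis genes were rhythmic in 20 of 20 cases in low salt day fed (alone, 20, list adjusted p = 9.3e-07) around ZT4.65 and in 18 of 20 in high salt day fed (alone, 18, list adjusted p = 1.37e-06) around ZT4.47. Hmgcs1, an early enzyme of that pathway, peaked at ZT4.12 in low salt day fed (amplitude 0.84 ± 0.10). All 7 MHC class II genes were rhythmic in both day-fed groups, around ZT11.3 under low salt (alone, 7, list adjusted p = 0.0214) and ZT1.04 under high salt (alone, 7, list adjusted p = 0.0019). The high salt day fed peaks include ZT0 and ZT12, whose labels could not be settled above. With cosine and sine terms 3128 genes were rhythmic in that group, and 547 without these times as well. In MR knock out immediate early genes were rhythmic in 9 of 10 cases (alone, 9, list adjusted p = 8.53e-05) around ZT6.49 and T cell genes in 5 of 5 (alone, 5, list adjusted p = 0.00361) around ZT4.73. In low salt night fed, xenobiotic metabolism genes (12 of 16, alone, 13, list adjusted p = 1.06e-04) peaked around ZT13.9 and antimicrobial and epithelial defence genes (10 of 15, alone, 11, list adjusted p = 0.00166) around ZT2.8. Lists with fewer than 3 measured members were not tested. Mitochondrial, neuron and glia, endothelial and acinar lists had 0, fibroblast, B and plasma cell and adipocyte 1, and myeloid and skeletal muscle 2.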
